A study of Homo sapiens with 12 samples.

How the data were processed

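RNA from human coronary artery endothelial cells grown on 5 micropattern shapes or on an unpatterned collagen I region was amplified, labelled with biotin and hybridised to Illumina bead arrays, per the labels' protocols. The 12 arrays form 6 groups of 2, and group and replicate number were taken from the labels, which spell the round shape in more than a single way (disk is used throughout). Per the file headers, the deposited scanner table holds an intensity for each of 47322 probes on each array, on a linear scale, together with a detection p-value against negative control beads. The column means differ between arrays, so these intensity values had not been normalised between arrays, and no background had been subtracted. The authors also deposited an intensity table in which each array is multiplied by a single factor, between 0.836 and 1.29, so that all arrays have a mean of 413.6, on a linear scale and without background subtraction. The scanner software and its version are not given in the sources used here. Gene symbols and IDs came from the platform annotation given with the data, and among tested probes 18335 had a single symbol, 5 had several and 6775 had none. Probes without a single symbol were tested but not named.

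The main values were made from the scanner table in R 4.3.3 with limma 3.58.1. The neqc function subtracted background estimated from the detection p-values, applied quantile normalisation, added an offset of 16 and took log2 values. A probe was tested when its detection p-value was below 0.05 on at least 2 of the 12 arrays, which left 25115 probes of 13351 genes. Quantile normalisation gives every array the same distribution, so a change of all transcripts together cannot be seen. For a gene undetected on every array of a group, a lower bound of the fold is given against the lowest log2 value of any detected probe on each of those arrays. This bound carries no sampling error. Brightness per array is given as the mean scanner intensity, and the number of arrays sets the precision. The fit had 6 residual degrees of freedom and gained 4.21 from the prior.

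A linear model with a mean per group was fitted to all 12 arrays with limma, and empirical Bayes moderation was applied. The contrasts were the mean of the 5 patterns against the control, each pattern against the control, a moderated F test among the 5 patterns, and the 10 pairs of patterns with 1 adjustment over all probes and pairs. All tests were two-sided with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. Replicate numbers were not used as pairs, because the differences of replicate 1 from replicate 2 hardly correlated between groups (r = 0.000718 to 0.0389 over 15 pairs of groups). No array position or chip is named in the sources used here.

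The 32 gene lists (23 of pathways and 9 of cell type markers) were tested with camera at a preset correlation of 0.01, with the brightest probe per gene and lists of at least 5 detected genes, which left 30. The pathway lists cover YAP and TAZ targets, SRF and actin, focal adhesion and integrins, DNA replication, mitosis, p53 and CDK inhibitors, immediate early genes, the KLF2 flow response, NF-kB and adhesion, the interferon response, extracellular matrix, VEGF and tip cells, Notch, TGF-beta and BMP, endothelial junctions, cholesterol and SREBP, hypoxia and glycolysis, heat shock, the unfolded protein response and ATF4, ribosomal proteins, oxidative phosphorylation and histones. The result of 1 further pathway list is not reported here. The marker lists cover endothelial, arterial, venous, lymphatic, smooth muscle and pericyte, fibroblast, leukocyte, epithelial and mesenchymal transition genes. Camera p-values were adjusted over the 30 lists, or over the 150 pairs of list and pattern.

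Grouping, contrasts, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names the 12 largest rises and the 12 largest falls past the threshold with all patterned arrays on the same side of both controls, the 4 largest rises and falls of each pattern, the 15 genes with the smallest F test p (each gene by its brightest probe, as in the whole rule), and 4 members (2 where fewer than 3 passed) of each list. Sex-linked transcripts were not named. The contrast of the disk with the other 4 patterns was added after the data were seen.

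The alternatives tried were no background correction, an offset of 50, centring each array on its median in place of quantile normalisation, the authors' scaled values, no detection filter, a stricter filter (detection p-value below 0.01 on all arrays of a group), the replicate number as a block, array weights, an intensity trend with robust moderation, a minimum of 1.5-fold, leaving out each array in turn, fits on only the arrays compared, camera with an estimated correlation, the mean of all probes of a gene, and fry. A chip block could not be run. Leaving out both disk arrays or both L arrays was added after the data were seen.

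The steps were tested on simulated data with known changes. With 67, 67 and 66 of 25115 probes changed by 0.5, 1 and 2 on the log2 scale, the comparison of the 5 patterns with the control recovered 40.3%, 98.5% and 100% with 9 false calls, the Y against the control 13.4%, 94.0% and 100% with 6, and the F test among patterns 4.48%, 71.6% and 100% with 9. A single list shifted by -0.3 over 13351 genes was called for the 5 patterns against the control, and no other of the 30 lists was. The noise was drawn independently for each gene, so this could not show false list calls that arise from correlation between genes.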

Results

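Messenger RNA was measured in human coronary artery endothelial cells, which line the arteries of the heart and were used here as commercially supplied primary cells below passage 5. The cells grew for 24 h on collagen I islands of 1600 µm² shaped as a Y, a crossbow, an H, an L or a disk, each of which confines the spreading of a cell to that outline. Control cells grew on an unpatterned collagen I region of the same kind of plate. Each of the 6 groups was hybridised to 2 arrays, which makes 12 arrays in total. The labels give 18 biological replicates per shape but not how these were divided over the 2 arrays, so p-values rest on the spread between arrays, which may be technical. Cell number or density on each surface is not given in the sources used here.

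The mean scanner intensity ran from 320.45 on L replicate 2 to 494.74 on control replicate 1, and both control arrays were brighter than every patterned array. Between 19142 and 21399 of the 47322 probes were detected on an array, with the median detected probe at 1.99 to 2.60 times the background. Across probes, which are not independent replicates, the 2 arrays of a group correlated at r = 0.991 to 0.994, control with patterned arrays at 0.979 to 0.983 and arrays of different patterns at 0.989 to 0.993. The number of arrays limits the precision of every value.

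**Figure D1:**
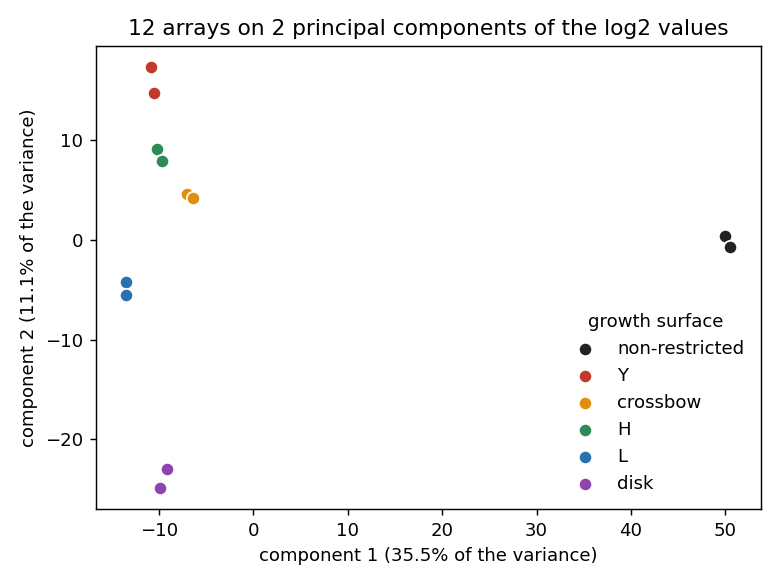
The 12 arrays on the leading principal components of the normalised log2 intensities, with component 1 (35.5% of the variance) on the x axis, component 2 (11.1%) on the y axis, both in arbitrary units, and a point per array coloured by growth surface. The control arrays lie at 49.9 and 50.5 on component 1 and the patterned arrays between -13.5 and -6.37, while component 2 runs from -24.9 on the disk to 17.4 on the Y.

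The series asks how the geometry of the growth surface goes with the transcriptome, and the broadest comparison sets the mean of the 5 patterns against the unpatterned region. As lists, genes of Notch signalling were higher in patterned cells and genes of mitosis and DNA replication lower, at a preset and at an estimated correlation between genes. Lists of arterial markers and of TGF-beta and BMP genes were called upward at the preset correlation, but had adjusted p = 0.0689 and 0.133 with an estimated correlation. TMEM100 (gene ID 55273), a membrane protein that BMP signalling through ALK1 induces in endothelium, rose most, by 3.24 ± 0.08 on the log2 scale or 9.46-fold (SE, n = 10 patterned and 2 control arrays). RGS4 (gene ID 5999), which dampens signalling by G protein coupled receptors, showed the largest fall and fell by 3.14 ± 0.09 or 8.83-fold. Values after ± are standard errors of the fit unless marked as SD, and n is the same for every comparison of the 5 patterns with the control.

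Among the largest rises, ALPL (gene ID 249), tissue-nonspecific alkaline phosphatase, rose by 3.18 ± 0.13 and was detected on 1 of the 2 control arrays. F2RL3 (9002), the thrombin receptor PAR4, rose by 2.77 ± 0.10 at the probe used, which was also detected on 1 of the 2 control arrays, while another detected probe of this gene stood at 0.23. BMF (90427), a pro-apoptotic BCL2-family protein, rose by 2.74 ± 0.09. PTGS2 (5743), the inducible cyclooxygenase of prostaglandin synthesis, rose by 2.40 ± 0.10. PRRX2 (51450), a homeobox transcription factor, was undetected on both control arrays and at least 3.61-fold higher on the patterns. SPRY1 (10252), a feedback inhibitor of receptor tyrosine kinase signalling, rose by 1.91 ± 0.08. DRAXIN (374946), a secreted axon guidance protein, rose by 1.90 ± 0.10, while another called probe of it stood at 0.88. The other detected probes of BMF, PTGS2 and SPRY1 stood at 2.81, 2.30 and 1.97. ANKRD1 (27063), a target of the mechanosensitive regulators YAP and TAZ, rose by 1.89 ± 0.09. SEMA3G (56920), a secreted semaphorin, rose by 1.87 ± 0.09. SLC7A8 (23428), a neutral amino acid transporter, and TCIM (56892) both rose by 1.84, with errors of 0.11 and 0.09.

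Among the largest falls, NRG1 (gene ID 3084), the ERBB receptor ligand neuregulin, changed by -2.71 ± 0.11 and DKK1 (22943), a secreted Wnt inhibitor, by -2.42 ± 0.09. SPAAR (158376), a small polypeptide that restrains mTORC1, changed by -2.37 ± 0.11. PNMA2 (10687) changed by -2.24 ± 0.12, the neutrophil chemokine CXCL1 (2919) by -2.21 ± 0.18, and FABP4 (2167), a fatty acid carrier, by -2.19 ± 0.13. Cell division genes were TOP2A (7153), the topoisomerase that untangles chromosomes, at -2.18 ± 0.14, UHRF1 (29128), needed for maintenance of DNA methylation, at -2.16 ± 0.11, and MAD2L1 (4085), of the spindle checkpoint, at -2.04 ± 0.14. APLN (8862), the peptide ligand apelin, changed by -2.10 ± 0.13 and STEAP1 (26872), a metalloreductase, by -2.05 ± 0.14. Other detected probes, all called downward, changed less: -1.62 and -0.91 for NRG1, -0.73 for DKK1 and -1.70 for STEAP1. The adjusted p of these 24 genes lay between 4.25e-08 and 2.34e-05, and all 10 patterned arrays stood on the same side of both controls in each.

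**Figure D2:**
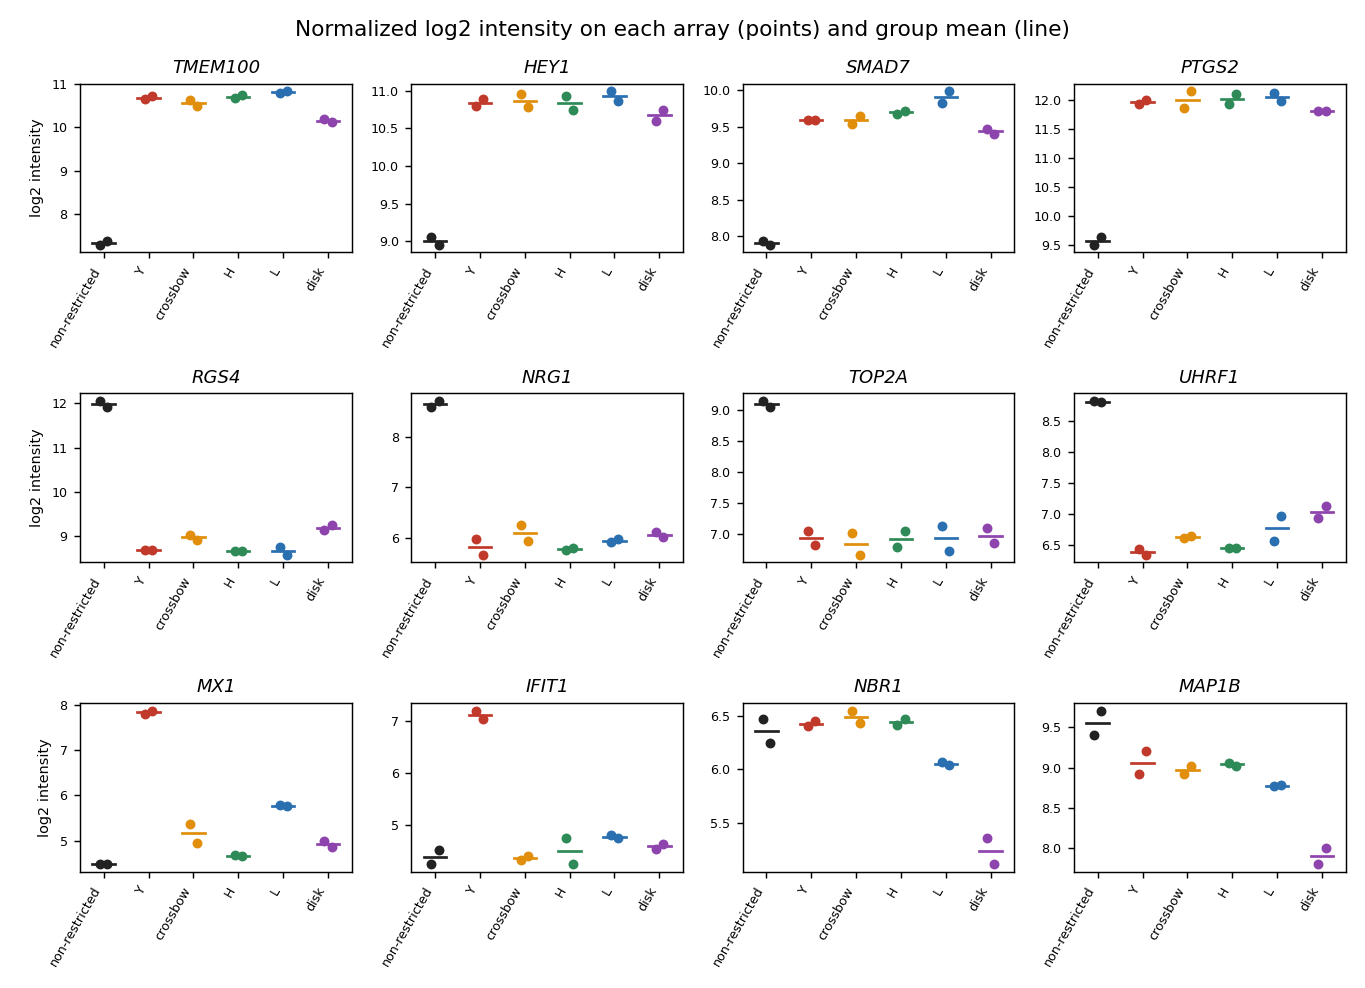
Normalised log2 intensity (y axis, scaled per panel) of 12 genes on each array, with a point per array, a line at the mean of the 2 arrays, and the growth surface on the x axis. TMEM100 stands at 7.30 and 7.38 on the control arrays and between 10.1 and 10.8 on the patterned ones, MX1 and IFIT1 stand highest on both Y arrays, and NBR1 and MAP1B lowest on both disk arrays.

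Over all genes, limma called 6733 of the 25115 tested probes, 3223 higher and 3510 lower on the patterns, which covered 2083 genes upward and 2093 downward. A change of at least 2-fold was reached by 249 of the higher and 312 of the lower probes. In 4450 of 13336 genes (33.4%) all 10 patterned arrays lay on the same side of both controls. Chance gives 3.03% if all 12 arrays are independent, but a much higher share if the 2 arrays of a group move together. The labels do not settle which holds, so this share alone does not show an excess. The split depends on the scaling: 47.9% of the calls were higher here, 11.3% when each array was centred on its median and 67.9% with the authors' values. These alternatives put the median change of the 25115 tested probes at -0.20 and 0.13. Median centring aligned the median over all 47322 probes, most of them undetected on each array, so it aligned the arrays near their background level. All changes are therefore relative to the bulk of the probes, and of the 6733 calls 4614 were kept under median centring and 5862 with the authors' values, and none became a call in the opposite direction. Without control replicate 1 the fit called 3780 probes, and without control replicate 2 it called 3582.

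The mitosis list moved furthest. Of the 30 genes of mitosis and G2, 26 fell and 4 did not pass (27 fell adjusted over the list alone), with a median change of -1.34. The list had a camera adjusted p of 3.28e-19. Examples are UBE2C, which tags mitotic proteins for destruction, at -1.41 ± 0.08, cyclin A2 (CCNA2) at -1.59 ± 0.10 and the mitotic kinase AURKB at -1.30 ± 0.10. Of 22 detected genes of DNA replication and S phase, 18 fell and 4 did not pass (19 fell adjusted over the list alone), with a median of -0.82 and an adjusted p of 9.6e-11. The replicative helicase subunit MCM4 changed by -1.31 ± 0.09, the flap nuclease FEN1 by -1.24 ± 0.10 and thymidylate synthase (TYMS) by -1.07 ± 0.09. Both calls held with an estimated correlation, at adjusted p = 0.00124 and 0.0237. Of 16 genes of the p53 pathway and the CDK inhibitors, 4 rose and 2 fell (7 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.119). In it the stress cytokine GDF15 rose by 1.19 ± 0.12, TP53INP1 by 0.67 ± 0.10 and the CDK inhibitor CDKN1B (p27) by 0.50 ± 0.09, while CDKN2B (p15) changed by -0.70 ± 0.08. Of 12 histone genes, 5 rose and 3 fell (6 and 3 adjusted over the list alone; list adjusted p = 0.191). Among them were H2AC18 at 0.94 ± 0.09, H2AC20 at 1.08 ± 0.11, H2BC21 at 0.90 ± 0.10 and H2BC5 at 0.73 ± 0.09.

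Genes of Notch signalling and of arterial endothelium rose together. Of 14 Notch genes, 12 rose and 2 did not pass (12 adjusted over the list alone), with a median of 0.70. The list passed at an adjusted p of 1.79e-07, and at adjusted p = 0.0348 with an estimated correlation. The Notch target HEY1 rose by 1.83 ± 0.09, the arterial ligand EFNB2 by 1.35 ± 0.09, the glycosyltransferase LFNG, which modifies Notch receptors, by 1.20 ± 0.09 and the ligand JAG2 by 1.16 ± 0.10. All 9 detected arterial markers rose (9 adjusted over the list alone), with a median of 1.12. The list passed at an adjusted p of 1.06e-07, but had adjusted p = 0.0689 with an estimated correlation. This list shares 5 genes with the Notch list, and outside it the netrin receptor UNC5B rose by 1.69 ± 0.11 and the transcription factor SOX17 by 1.25 ± 0.10. Of the 6 venous markers 4 were detected, too few for a list test: ACKR1 changed by -0.75 ± 0.12 and EPHB4 by 0.33 ± 0.10, the latter -0.036 when arrays were centred on their medians.

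Of 21 TGF-beta and BMP genes, 9 rose and 2 fell (10 and 2 adjusted over the list alone), with a median of 0.23. The list passed at an adjusted p of 0.00478, but had adjusted p = 0.133 with an estimated correlation. The inhibitory SMADs rose, SMAD7 by 1.74 ± 0.08 and SMAD6 by 1.16 ± 0.09. The ligand BMP2 rose by 1.39 ± 0.08, while the ligand BMP4 fell by 1.93 ± 0.12 and was detected on 4 of the 10 patterned arrays.

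Among lists tied to cell shape and force, the actin and contractile targets of SRF passed, with 2 of 21 higher and 9 lower (3 and 11 adjusted over the list alone). The median was -0.24 and the adjusted p 0.0339, but adjusted p = 0.344 with an estimated correlation. In it the actin-bundling LIMA1 changed by -1.04 ± 0.08 and caldesmon (CALD1) by -0.89 ± 0.09, while myosin light chain kinase (MYLK) rose by 0.79 ± 0.09 and smooth muscle actin (ACTA2) by 0.46 ± 0.08. The call was also lost without control replicate 1, under median centring and under a stricter detection filter. Of 21 YAP and TAZ targets, 5 rose and 9 fell (5 and 11 adjusted over the list alone), and the list did not pass (adjusted p = 0.119). ANKRD1 was its largest rise, whereas CCN1, another target, changed by -1.11 ± 0.09, TGFB2 by -1.55 ± 0.14 and CRIM1 by -0.94 ± 0.09. Of 24 focal adhesion and integrin genes, 8 rose and 5 fell (10 and 6 adjusted over the list alone; list adjusted p = 0.595). The scaffold NEDD9 rose by 1.48 ± 0.11, integrin beta 4 (ITGB4) by 1.20 ± 0.12 and integrin alpha 2 (ITGA2), a subunit of a collagen receptor, by 0.68 ± 0.08, and caveolin 1 (CAV1) changed by -1.05 ± 0.09. Of 27 extracellular matrix genes, 9 rose and 3 fell (11 and 4 adjusted over the list alone; list adjusted p = 0.0698). Its members included the protease MMP10 at 1.04 ± 0.08, MGP, an inhibitor of calcification and of BMPs, at 0.87 ± 0.09, perlecan (HSPG2) at 0.77 ± 0.09 and lysyl oxidase (LOX) at -0.75 ± 0.10.

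In signalling and inflammation, the immediate early genes passed narrowly, with 8 of 17 higher and 3 lower (10 and 3 adjusted over the list alone). The median was 0.36 and the adjusted p 0.048, but adjusted p = 0.178 with an estimated correlation. JUNB rose by 1.08 ± 0.11, JUN by 0.80 ± 0.10, ATF3 by 0.73 ± 0.09 and the phosphatase DUSP5 by 0.62 ± 0.12. This call was lost without control replicate 1, either crossbow array, either H array or disk replicate 2, and under several other settings of the processing. Of 16 genes of NF-kB signalling, inflammation and adhesion, 6 rose and 5 fell (7 and 5 adjusted over the list alone; list adjusted p = 0.482). Examples were the cytokine IL6 at -1.22 ± 0.10 and the monocyte chemokine CCL2 at -1.27 ± 0.12 beside the changes in PTGS2 and CXCL1. Of 16 genes of the KLF2 flow response, 8 rose and 3 fell (9 and 3 adjusted over the list alone; list adjusted p = 0.11). Changes included KLF4 at 0.96 ± 0.13, prostaglandin D synthase (PTGDS) at 0.88 ± 0.10 (detected on 1 of the 2 control arrays), the lipid phosphatase PLPP3 at 0.77 ± 0.10 and the angiopoietin receptor TEK at 0.53 ± 0.08. Of 17 genes of VEGF signalling and tip cells, 7 rose and 3 fell (8 and 4 adjusted over the list alone; list adjusted p = 0.119). Among them were the VEGF receptor KDR at 1.03 ± 0.08 and PDGFB at 1.27 ± 0.10 beside UNC5B and APLN. Of 22 interferon-response genes, 7 rose and 3 fell (7 and 3 adjusted over the list alone; list adjusted p = 0.383). MX1, an antiviral GTPase, was undetected on the controls and at least 1.92-fold higher on the mean of the patterns. However, MX1 was also undetected on the H, where the limma test did not pass (adjusted p = 0.394) and no size can be given. The mean for IFIT1, detected only on the 2 Y arrays, was at least 1.26-fold higher, and no other pattern passed. IRF7 rose by 0.53 ± 0.11 and IFI44 changed by -0.42 ± 0.11.

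In metabolism and stress, 7 of 19 genes of oxidative phosphorylation fell (8 adjusted over the list alone) and 12 did not pass. The median was -0.26 and the adjusted p 0.0326, but adjusted p = 0.133 with an estimated correlation. The ATP synthase subunits ATP5MC3, ATP5F1B and ATP5F1A changed by -0.88 ± 0.10, -0.39 ± 0.09 and -0.34 ± 0.08 and cytochrome c (CYCS) by -0.47 ± 0.10. The list call was lost without control replicate 2 and under a stricter detection filter. Of 16 genes of hypoxia and glycolysis, 3 rose and 5 fell (4 and 5 adjusted over the list alone; list adjusted p = 0.918). The median of this list was 0.09, whereas its test pointed downward. NDRG1 rose by 0.89 ± 0.10 and the histone demethylase KDM3A by 0.84 ± 0.14, while the glycolytic enzymes LDHA and PGK1 changed by -0.76 ± 0.09 and -0.79 ± 0.10. Of 19 genes of the unfolded protein response and ATF4, 9 rose and 2 fell (9 and 2 adjusted over the list alone; list adjusted p = 0.119). Its members included DDIT3 at 0.87 ± 0.09, the mTORC1 inhibitors DDIT4 and SESN2 at 0.72 ± 0.11 and 0.70 ± 0.09, and PHGDH of serine synthesis at -0.51 ± 0.08. Of 13 heat shock genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone; list adjusted p = 0.213). Examples were the inducible chaperones HSPA6 at 1.00 ± 0.12, HSPA1A at 0.62 ± 0.12 and HSPA1B at 0.59 ± 0.08 and the cochaperone BAG3 at 0.48 ± 0.09. Of 17 genes of cholesterol synthesis and SREBP, 1 rose and 4 fell (1 and 4 adjusted over the list alone; list adjusted p = 0.608). Changes included SC5D at 0.62 ± 0.09, MSMO1 at -0.52 ± 0.11, INSIG1 at -0.38 ± 0.10 and fatty acid synthase (FASN) at -0.30 ± 0.09. Of 26 ribosomal protein genes, 23 did not pass and the list adjusted p was 0.796. RPL5 stood at 0.33 ± 0.08 (-0.0058 under median centring), RPL6 at -0.28 ± 0.09, RPS6 at -0.31 ± 0.10 and RPL7, which did not pass, at 0.24 ± 0.09 (-0.12 under median centring). All 26 missed the threshold adjusted over the list alone.

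The other lists of cell identity did not pass as lists. Of 15 endothelial markers, 4 rose and 4 fell (4 and 4 adjusted over the list alone; list adjusted p = 0.608). Among them were TIE1 at 0.71 ± 0.08, von Willebrand factor (VWF) at 0.57 ± 0.08 and claudin 5 (CLDN5) at -0.69 ± 0.10. The list's median of -0.04 differed in sign from its mean of 0.08 and from the test. Of 14 junction genes, 4 rose and 1 fell (4 and 2 adjusted over the list alone; list adjusted p = 0.304). Its members included the phosphatase PTPRB at 1.07 ± 0.09, plakoglobin (JUP) at 0.94 ± 0.10 and JAM3 at 0.48 ± 0.09. Of 6 lymphatic markers, RELN alone rose, by 1.47 ± 0.08 (1 adjusted over the list alone, list adjusted p = 0.191). FLT4, undetected on the controls and detected on 4 of the 10 patterned arrays, did not pass. Its patterned mean lay 1.07-fold above the lowest detected level on the controls. Of 6 smooth muscle and pericyte markers, 1 rose and 3 fell (1 and 4 adjusted over the list alone; list adjusted p = 0.119). Examples were SMTN at -0.65 ± 0.11, RGS5 at -0.47 ± 0.08 and CNN1 at -0.44 ± 0.10, the last detected on 2 of the 10 patterned arrays and at 0.066 in the authors' values. Of 5 fibroblast markers, FAP fell by 0.34 ± 0.09 and COL1A1, undetected on the controls, did not pass (1 higher and 1 lower adjusted over the list alone, list adjusted p = 0.626). The patterned mean of COL1A1 lay 1.16-fold above the lowest detected level on the controls. The 5 leukocyte markers had a median of -0.01 (list adjusted p = 0.662). Examples were CD68 at 0.26 ± 0.09 (adjusted p = 0.0503, and -0.14 under median centring) and ITGAM, undetected on the controls and detected on 2 of the 10 patterned arrays (adjusted p = 0.333). Of the 7 epithelial markers 4 were detected, too few for a list test, with KRT18 at -0.49 ± 0.22 (adjusted p = 0.135) and KRT19 at -0.20 ± 0.11 (adjusted p = 0.222). Of 11 genes of mesenchymal transition, 2 rose and 2 fell (2 and 2 adjusted over the list alone; list adjusted p = 0.776). Among them were the transcription factors SNAI1 at 1.32 ± 0.16 and SNAI2 at -0.74 ± 0.09 and N-cadherin (CDH2) at -0.46 ± 0.09.

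**Figure D3:**
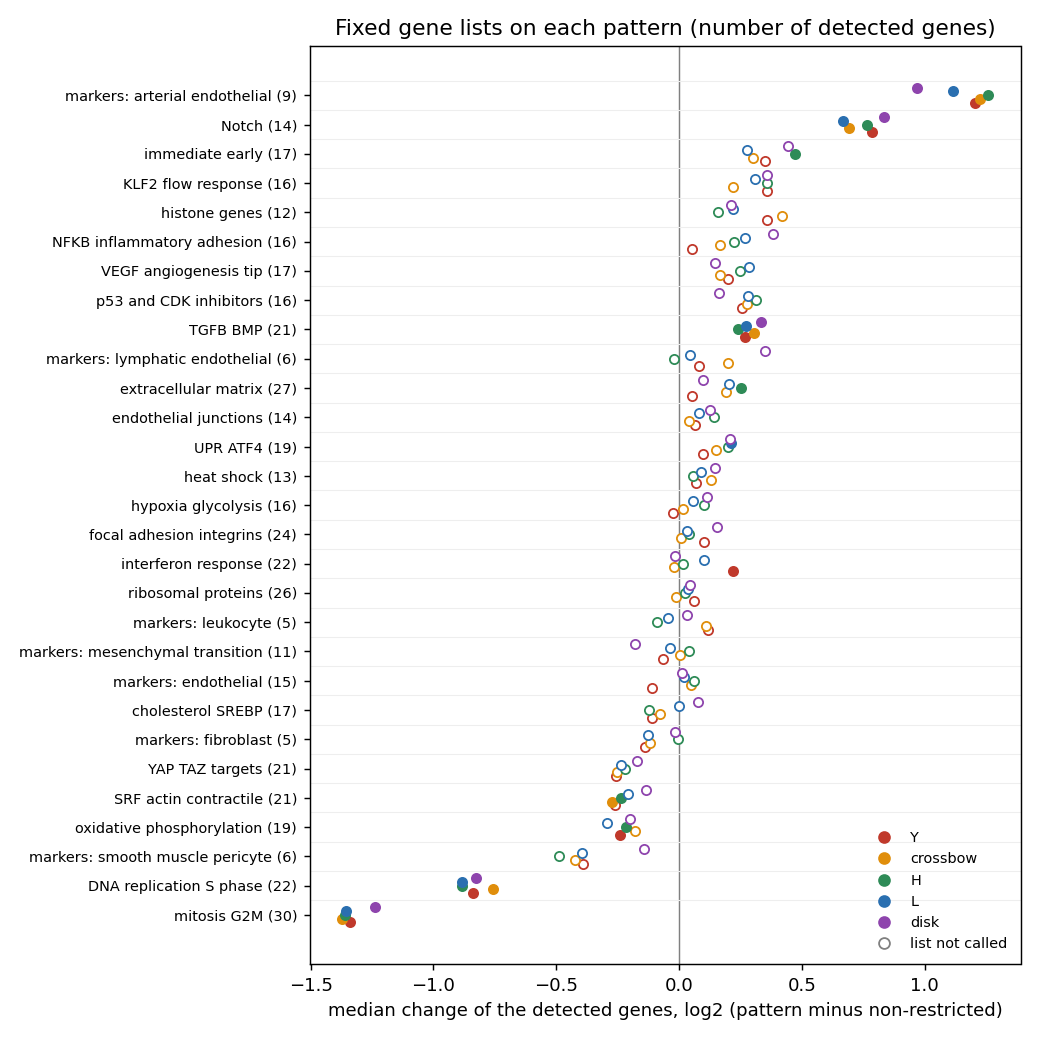
Median log2 change of the detected genes of each list shown (y axis, number of detected genes in brackets) on each pattern against the control (x axis), with filled points where camera called the list and open points where it did not. The mitosis list lies between -1.37 and -1.24 and the arterial list between 0.97 and 1.26 on the 5 patterns.

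Each pattern was also set against the control on its own. TMEM100, ALPL, RGS4 and NRG1 were among the largest changes on every shape. TMEM100 rose by 3.34 ± 0.11 on the Y, 3.22 on the crossbow, 3.37 on the H, 3.47 on the L and 2.81 on the disk (SE 0.11 for each, n = 2 arrays per group). ALPL rose by 2.99, 3.12, 3.20, 3.38 and 3.20 in the same order (SE 0.17), and RGS4 changed by -3.29, -3.01, -3.32, -3.31 and -2.78 (SE 0.11). NRG1 changed by -2.84, -2.55, -2.88, -2.71 and -2.59 (SE 0.14). F2RL3 and BMF completed the largest rises on the crossbow (2.78 and 2.67), the H (2.78 and 2.77), the L (2.94 and 2.79) and the disk (2.71 and 2.78). On the Y their place was taken by the interferon-induced genes MX1 (gene ID 4599), undetected on the controls and at least 8.55-fold higher, and IFIT1 (3434), at least 5.22-fold higher. The other large falls were DKK1 on the Y, crossbow and H (-2.52, -2.44 and -2.61), UHRF1 on the Y (-2.43), SPAAR on the crossbow, L and disk (-2.65, -2.51 and -2.24), CXCL1 on the H (-2.42), FABP4 on the L (-2.57) and TOP2A on the disk (-2.12). Other detected probes of NRG1, DKK1 and F2RL3 changed less on the shapes named here for these genes.

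The fit called 4586 probes for the Y (2266 higher and 2320 lower), 3922 for the crossbow (1937 and 1985), 4534 for the H (2233 and 2301), 5252 for the L (2541 and 2711) and 5154 for the disk (2478 and 2676). Centred on array medians, the split turned to 1265 higher and 5536 lower for the Y, 865 and 5181 for the crossbow, 820 and 7990 for the H, 489 and 11581 for the L, and 1337 and 4354 for the disk. In the authors' values it was 5027 and 4008, 5349 and 3775, 10977 and 4809, 12293 and 5488, and 5390 and 4113 in that order. Leaving out an array of the pattern or of the control lowered a count to between 2617 and 3109 probes for the Y, 2052 and 2187 for the crossbow, 2454 and 2636 for the H, 2942 and 3497 for the L and 2791 and 3149 for the disk.

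Across shapes, 1081 probes were called higher and 1163 lower on all 5 patterns, where independent lists would share 0.155 and 0.193. Of the 8389 probes called on any pattern, 5 had calls in opposite directions. The log2 changes of 2 patterns correlated across probes at r = 0.791 to 0.86, with a mean of 0.835 and a mean covariance of 0.139. Because the patterns share their control arrays, simulated data without any change gave r = 0.499 and a covariance of 0.0153, with 0 probes called on all 5 patterns. The sign was the same on all 5 patterns for 55.7% of probes, against 33.3% in the simulation. The simulated noise was independent for each array, so hardly any call could arise and no deviation was common to the 2 control arrays. How many calls such a deviation would place on all 5 patterns cannot be told from it.

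Camera called 33 of the 150 pairs of list and pattern. Mitosis, DNA replication, Notch, arterial and TGF-beta and BMP genes were called on every shape. With an estimated correlation the arterial list had adjusted p = 0.0678 to 0.0915 and the TGF-beta and BMP list 0.148 to 0.173. Mitosis genes that fell numbered 27 on the Y and 26 of 30 on each other pattern (27, 27, 28, 27 and 26 adjusted over the list alone on the Y, crossbow, H, L and disk). Notch genes that rose ranged from 9 on the crossbow to 11 of 14 on the H, L and disk (11, 12, 12, 11 and 11 adjusted over the list alone). With an estimated correlation, 15 pairs remained, those of mitosis (adjusted p = 0.00147), DNA replication (0.0296) and Notch (0.0384 to 0.0471). Interferon-response genes were called on the Y, where 7 of 22 rose (8 adjusted over the list alone; adjusted p = 0.0118, but adjusted p = 0.102 with an estimated correlation). Oxidative phosphorylation was called on the Y and H (adjusted p = 0.0114 and 0.0496, but adjusted p = 0.102 and 0.172 with an estimated correlation). The SRF targets were called on the crossbow and H (0.0165 and 0.0496, but adjusted p = 0.298 and 0.366 with an estimated correlation). Immediate early and matrix genes were called on the H (0.0276 and 0.0165, but adjusted p = 0.168 and 0.128 with an estimated correlation). The unfolded protein response was called on the L (0.0496, but adjusted p = 0.303 with an estimated correlation). Whether these lists differed between the shapes was not tested by these calls.

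Whether the shape itself, at equal area, went with expression was tested among the 5 patterns. Differences called between shapes were fewer than those from the control, and they lay mainly in a set of probes that were lowest on the disk, while the interferon-induced MX1 and IFIT1 were highest on the Y. MX1 was highest on the Y, at 7.83 ± 0.04 (SD, n = 2 arrays, as for each mean of a single shape) against 4.67 ± 0.02 on the H, at least 8.39-fold (adjusted p = 6.26e-05). IFIT1 stood at 7.12 ± 0.11 on the Y against 4.37 ± 0.05 on the crossbow, at least 5.19-fold (adjusted p = 0.000575), and both Y arrays lay above the 10 others in both genes. On the disk, NBR1 (gene ID 4077), a receptor of selective autophagy, was lowest at 5.23 ± 0.18 against 6.49 ± 0.08 on the crossbow, and MAP1B (4131), a microtubule-associated protein, at 7.90 ± 0.15 against 9.06 ± 0.21 on the Y.

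The moderated F test called 34 of 25115 probes, covering 22 genes with a symbol, 14 of them called at their brightest probe and 8 only at another probe, which are not named. Of these probes 28 were lowest on the disk and 20 highest on the Y, and 4095 probes had an unadjusted p below 0.05. Besides MX1, IFIT1, NBR1 and MAP1B, called genes lowest on the disk were the MAP kinase phosphatase DUSP4 (gene ID 1846), RSRP1 (57035), NOMO3 (408050), SFR1 (119392), EIF3CL (728689), the G protein subunit GNG12 (55970), PDLIM5 (10611), which binds actin-associated alpha-actinin, and the proteasome ATPase PSMC4 (5704). Their gap to the highest shape ran from 0.86 for RSRP1 to 1.16 for PDLIM5 on the log2 scale, with adjusted p from 0.026 to 0.0443. NOMO3 and EIF3CL have close paralogs that their probes may also bind. Highest on the disk were ENPP1 (5167), a pyrophosphatase that restrains mineralisation, 0.89 above the L, and fatty acid synthase FASN (2194), 0.94 above the Y (adjusted p = 0.048 for both). ENPP1 was detected on 1 of the 2 L arrays, and its gap fell to as little as 0.07 over the refits. UACA (55075) was 1.09 lower on the disk than on the Y and missed the threshold (adjusted p = 0.0539).

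Over the 10 pairs of shapes with a single adjustment, 48 probes were called in at least 1 pair. The Y and the disk differed in 31 probes, as did the H and the disk, the crossbow and the disk in 8, the L and the disk in 4, and each pair without the disk in 1 to 3. The F count ranged with the processing from 3 probes with the replicate number as a block to 1477 without background correction and 8258 in the authors' values. With any single array left out, the F test called 1 to 4 probes and the pairs 1 to 14, with the lowest counts without Y replicate 2. MX1 kept its F test call in all 23 refits and IFIT1 in the 21 that tested it (it was not tested without Y replicate 1 or 2), whereas the 12 other called genes named here lost it in 14 or more of 23. The 8 genes called only at another probe were not refitted one by one.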

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

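The tests of array brightness, of other splits of the arrays, of the length of called genes, of other probes of the same genes and the contrast of the disk with the other patterns were chosen only after the result was seen. The 14 genes given here stood out because their levels differed between pattern shapes in the F test at their brightest probe.

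MX1 was 3.16 higher on the Y than on the H and IFIT1 2.75 higher on the Y than on the crossbow (log2), both undetected on the lower shape and so at least 8.39-fold and 5.19-fold higher. NBR1 was 1.26 higher on the crossbow than on the disk. On the H, DUSP4 was 1.04, NOMO3 1.04 and GNG12 0.91 higher than on the disk. On the Y, RSRP1 was 0.86, SFR1 1.02, EIF3CL 1.13, MAP1B 1.17, PDLIM5 1.16 and PSMC4 0.90 higher than on the disk. ENPP1, detected on 1 of the 2 L arrays, was 0.89 higher on the disk than on the L, and FASN 0.94 higher on the disk than on the Y. In each gene both arrays of the higher shape lay above both arrays of the lower shape.

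The widest pattern is the difference between all patterned arrays and the 2 control arrays, which were also the brightest. Brightness alone is argued against, since its trend over the 10 patterned arrays accounted for a share of 0.0258 of the score difference (95% interval -0.0148 to 0.0665, or -0.0664 to 0.128 over the 5 pattern means). Cells of another type stay open. The largest median change of the smooth muscle, fibroblast, leukocyte and epithelial marker lists was -0.37, for smooth muscle. It lies below the 0.5 set beforehand, but by less than the spread of the 6 members (SD 0.39, from -0.65 to 0.46). With the 2 arrays of a group kept together there are 6 splits, too few for a share under 0.05. In fits with only 2 groups the real split called 5625 probes, and the highest of the other 5 called 63. In those other 5 the control arrays sat in the larger group, so their own difference widened the residual spread and lowered the counts. The low counts are therefore no standard for the real split. Confinement to a pattern stays open, as untested, and so does a difference in cell density or contact between the surfaces, which was not measured. An event shared by the control cultures or their RNA cannot be told apart from the surface. The labels tie neither control array to a separate culture, and all 5 patterns are compared with the same 2 arrays.

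Another pattern is a set of probes lower on the disk, 255 of the 332 called against the mean of the other 4 patterns, although 2267 of 2466 were higher under median centring, and leaving out disk replicate 1 or 2 left 2 and 0 calls. RNA integrity stays open. The length available was the span of the whole gene, introns included, and not that of the mature transcript. The length comparisons given here therefore cannot decide on RNA integrity. The difference did not follow length across all genes (Spearman's rank correlation -0.0105), and the 5301 genes at least as long as the median gene called lower had a median of 0.023 at their brightest probes. However, the correlation rests mostly on uncalled genes. The 173 genes with any probe called lower had a median length of 38.7 kb, against 26.9 kb over all genes and 34.5 kb for 58 genes with probes called only higher. A permutation test of rank sums over genes gave p = 0.0001 against all other genes and 0.563 against the 58. Single probes rather than whole genes remain a candidate explanation, since the 240 other detected probes of 143 of these 173 genes had a median of -0.039 where the called probes had -0.63. For calls of like size against the control, other probes had a median of -0.31. These calls were matched on size only: the called probe was the brightest in 267 of 573 genes there and in 38 of 143 on the disk. The called probe of each gene was picked by its smallest p, so smaller changes of its other probes arise partly by selection. The disk set may reflect transcript variants, probe chemistry or noise in the called probes more than gene levels. The disk shape itself stays open, as an untested biological explanation. An event shared by the disk cultures or their RNA cannot be told apart from the shape, because the labels tie neither disk array to a separate culture.

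A further pattern is the level of MX1 and IFIT1 on the Y, both called against the other 4 patterns, while the 20 other genes of the 22 in the interferon list did not pass. The list call on the Y against the control had adjusted p = 0.102 with an estimated correlation. For these 2 genes, a single outlying array is argued against by the values on the arrays. MX1 stood at 7.80 and 7.86 on the Y arrays and at 5.78 at most elsewhere. IFIT1 stood at 7.19 and 7.04, and at 4.80 at most elsewhere. A call on 2 arrays already favours genes that are high on both, so the count of such genes adds no support. In 7 of the 22 interferon genes, MX1 and IFIT1 included, both Y arrays lay above all 10 others. Chance gives 1.52% per gene if all 12 arrays are independent, and a much higher share if the 2 arrays of a group move together. Genes of a list may also move together. An event shared by the Y cultures or their RNA, such as an exposure unrelated to shape, cannot be told apart from the shape, because 0 of the Y arrays are tied by the labels to separate cultures. The Y shape itself therefore stays among the open explanations, as untested.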

How the results depend on the processing

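The contrast of the disk with the other patterns and the fits without all disk or all L arrays were chosen only after the result was seen. Of 122 named genes called in the patterned comparison, 92 kept direction and call in every refit. All 40 named calls for single patterns held in 918 refits, and 3 of 8 called lists (mitosis, DNA replication, Notch) in every setting. The named genes were picked from these data by large change or small p, so they do not stand for all calls. Of all 6733 calls of the patterned comparison, 4614 were kept under median centring. Without all disk arrays 6134 probes and 8 lists were called, without all L arrays 6371 and 8. Differences between shapes depended most on the processing: of the 14 genes called at their brightest probe, only MX1 was called in all 23 refits, and IFIT1 in the 21 that tested it (it missed the detection filter without Y replicate 1 or 2). With signals at 1.99 to 2.60 times background for the median detected probe, dim probes may limit the counts. A chip block was not run.

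In the order F test, pairs of patterns and disk against the other patterns, counts were 1477, 1938 and 1399 without background correction, 834, 1101 and 1054 with an offset of 50, and 250, 396 and 723 under the stricter filter, which also left 5 lists and tested fewer probes. No filter gave 92 for the pairs, array weights 78 for the pairs and 550 for the disk, trend and robust moderation 1255 and 1645 for the F test and pairs, and only the 10 patterned arrays 4 for the F test. With the replicate number as a block, the F test called 3 and the pairs 8. Median centring gave 10221 for the 5 patterns, 6046 for the crossbow, 8810 for the H, 12070 for the L, 4459 for the F test, 5121 for the pairs and 2466 for the disk against others. It turned RPL5 to -0.0058, RPL7 to -0.12, EPHB4 to -0.036 and CD68 to -0.14. The authors' values gave 16794 for the 5 patterns, 9035, 9124, 15786, 17781 and 9503 for the Y, crossbow, H, L and disk, 8258 for the F test, 9372 for the pairs and 2576 for the disk against others. There CNN1 turned to 0.066 and the focal adhesion, unfolded protein and endothelial lists pointed downward (adjusted p = 0.501, 0.994 and 0.95), while 16723 probes detected on no array had a median difference of 0.26, against 0.01 after neqc. A minimum of 1.5-fold left, by construction, 2629, 2858, 2417, 2782, 3169 and 3113 for the 5 patterns, Y, crossbow, H, L and disk, and 172 for the disk against others. The L fitted with only the 4 arrays compared gave 3095. An estimated correlation left 3 lists and 15 pairs of list and pattern, and fry, which tests whether a list moves at all, called 26 and 116. Other causes were not tested.

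Leaving out each array in turn, with the lone array assumed to vary like the others, gave 3582 to 6580 for the 5 patterns, 2617 to 4515 for the Y, 2052 to 3815 for the crossbow, 2454 to 4456 for the H, 2942 to 5213 for the L, 2791 to 5092 for the disk, 1 to 4 for the F test, 1 to 14 for the pairs, 0 to 238 for the disk against others, 6 to 8 lists and 27 to 37 pairs. The hypoxia list pointed upward without Y replicate 2 (adjusted p = 0.979, range 0.818 to 0.983) and the ribosomal list downward without control replicate 1 (0.952, range 0.357 to 0.952).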

Other observations

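The contrast of the disk with the other 4 patterns was chosen only after the result was seen. Both gene lists tested here were recorded as written down before the values of their members were looked at. However, both hypotheses came from these data, and the members EFNB2, LFNG, SMAD6 and CDKN1B are also named in the fixed lists. The tests were therefore not fully blind.

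Against the mean of the other 4 patterns, limma called 332 probes on the disk, 3 on the Y and 2 on the H, and 0 on the crossbow and on the L, where 1849 and 2419 probes had an unadjusted p below 0.05. Of the fixed lists, that of the interferon response was called downward on the disk (camera adjusted p = 0.0152, but adjusted p = 0.261 with an estimated correlation), with a median of -0.09 over 22 genes of which 2 fell. The values on the Y enter that mean.

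A hypothesis from TMEM100, HEY1, SMAD7 and NOG (NOG was chosen after its value was seen, 1.57 ± 0.11) is that signalling of the BMP9 and ALK1 type may be higher in patterned cells. Of 12 other targets of this pathway, 8 rose and 1 fell (9 and 1 adjusted over the list alone), with a camera p of 7.08e-06 and adjusted p = 0.0094 with an estimated correlation. ATOH8 rose by 1.21 ± 0.11, SMAD9 by 0.78 ± 0.12 and ID3 by 0.30 ± 0.08, while the known target ID1 stood at 0.28 ± 0.10 without passing and EDN1 changed by -0.74 ± 0.09. The list shares 4 genes with the Notch list and 5 with the TGF-beta and BMP list, and EFNB2 and HEY2 are also arterial markers. Without the Notch genes its camera p was 0.00744 over 8 genes. Of these, SMAD6, ATOH8, SMAD9 and ID3 passed upward and EDN1 downward, while ID1, ID2 (0.15 ± 0.09) and ENG (0.17 ± 0.10) did not pass. The condition written beforehand, that most detected targets pass upward, was met by the full list but not without the Notch genes. The full list goes with the hypothesis, but shared genes keep it from being independent of the lists in the report.

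A further hypothesis, from BMF and SPRY1, is that FOXO-type transcription may be higher in patterned cells. Of 15 detected genes linked to FOXO factors, which act when growth factor signalling is low, 9 rose and 1 fell (9 and 1 adjusted over the list alone), with a camera p of 5.5e-06 and adjusted p = 0.00568 with an estimated correlation. FBXO32 rose by 1.36 ± 0.09, KLHL24 by 1.20 ± 0.12, CCNG2 by 1.19 ± 0.09, IRS2 by 1.08 ± 0.09 and PIK3IP1 by 0.97 ± 0.12, while CITED2 changed by -0.40 ± 0.09. CDKN1B and SESN1 are also in the list of p53 genes and CDK inhibitors. The result is consistent with the hypothesis, but fewer dividing cells could raise some of these genes as well, which was not tested.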
